A study of Mus musculus with 12 samples.

How the data were processed

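Liver RNA of wild-type Balb/c mice aged 6 weeks was profiled by RNA-seq in 12 samples, 6 control and 6 severe acute pancreatitis (SAP) samples. Per the labels, the SAP samples were treated with caerulein, a cholecystokinin analogue that overstimulates the pancreas, and RNA was extracted from frozen liver with Trizol and made into standard Illumina libraries. Groups and sample numbers (control 3 to 8, SAP 10 to 15) were taken from the labels. The series' design text mentions a pair of mouse models, while the labels give 1 strain and only control and SAP, so whether all SAP samples come from 1 model is not given in the sources used here.

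The values deposited by the authors were read as TPM (transcript abundance scaled to a common total), in 1 table of 55487 rows with 12 sample columns and a gene symbol. No header or label names the unit. It was inferred from the values, which summed to between 993412 and 995793 in each library, had 2 decimals and shared no common step. Per the submitters' processing notes, edgeR was used, with no version and no role given. The aligner, the genome build, the annotation and the handling of strand and of reads shared between genes are not given in the sources used here. TPM keeps no sequencing depth, so the depth of each library is unknown and no counting interval was computed. All 12 sample columns were used and 0 were left out. Of the rows, 53409 carried a symbol found in GENCODE M21, and 120 rows repeated a symbol of another row.

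The main test fitted limma 3.58.1 in R 4.3.3, with a trend in the empirical Bayes step, to log2(TPM + 1). Genes with at least 1 TPM in at least 6 of the 12 libraries were kept, which left 11344 genes, and p-values were two-sided and adjusted with Benjamini-Hochberg at 0.05. The only term was the group, since the labels give no batch, pairing or sex. Log2 changes are on the log2(TPM + 1) scale, SAP minus control, and understate the change of genes with low values. Because the unit was TPM and not counts, the planned test of library totals was not applicable. Where rows shared a symbol, the row with the highest median kept it. That rule was set after the endoplasmic reticulum stress list had been seen. With the highest mean, the symbol Ddit3 went to a row listed at 0 in 9 of the 12 libraries, with a highest value of 298 TPM. With the highest-mean rule 13 of 15 tested members of the list rose.

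A total of 30 gene lists, 20 of pathways and 10 of cell type markers with 473 entries in all, was fixed before the data were examined, as were the tests, the thresholds and the rule for named genes. Each list with at least 3 tested members was tested with camera from limma at its preset inter-gene correlation of 0.01, adjusted over the 27 lists tested. Members were counted as risen, fallen or not past the threshold from the test over all genes, and again with p-values adjusted over the list alone. The rule for named genes took 2 kinds. The 10 largest increases and 10 largest decreases were taken among genes past the threshold, with separate groups and a mean of at least 5 TPM, passing over identifiers. From each list, the 3 tested members with the smallest adjusted p were taken. Other list members are given as examples and were chosen after their values were seen. Values of some named genes are not reported here.

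Alternatives were quantile normalization, scaling factors like those of TMM (trimming 30% of the ratios and 5% of the levels at each end), no filter, a mean of at least 5 TPM, limma without trend, a robust empirical Bayes step, a pseudocount of 0.1, camera with an estimated correlation, the rotation test fry, and leaving out each library. Alternatives for count data were not run on TPM. After the data were seen, 5 more were added: the library split by Xist described with the results as a term, the high Xist libraries alone, the low Xist libraries alone, all libraries without SAP 14 and control 5, and the highest mean for rows sharing a symbol. Measures of whole libraries were compared with exact two-sided permutation tests in scipy 1.17.1, adjusted over the 5 measures tested; the smallest p such a test can give here is 0.00216. Figures were drawn with matplotlib 3.10.9. Positions of genes come from GENCODE M21 on GRCm38.

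The pipeline was tested on simulated data before use. In 11344 simulated genes for SAP against control, 44 of 66 genes changed by 0.5 on the log2 scale were recovered, 61 of 67 changed by 1 and 67 of 67 changed by 2, with 11 false calls among 183. With no simulated change it called 0 genes and 0 lists. Both simulations drew genes independently of each other. The simulated changes touched far fewer genes than the 5043 past the threshold in the data, so the recovery and false-call rates may not hold there.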

Results

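Liver transcripts were measured by RNA-seq in 6 control liver samples and 6 from severe acute pancreatitis (SAP) after caerulein, to describe how the liver transcriptome differs between them. The deposited unit was read as TPM, which carries no depth, so depth per library is unknown. At least 1 TPM was reached by 11343 ± 102 genes (SD, n = 6) in controls and 11333 ± 356 (SD, n = 6) in SAP (exact permutation test, adjusted p = 0.950). The labels number the samples without stating that each came from a separate animal, so p-values measure the spread between these samples.

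In SAP livers transcripts of acute-phase proteins were higher and those of drug-metabolising enzymes lower. Saa3, a serum amyloid A gene, averaged 10.5 ± 2.58 TPM (SD, n = 6) in controls and 11114 ± 3002 TPM (SD, n = 6) in SAP, a log2 change of 9.90 ± 0.18 (SE; limma adjusted p = 7.12e-13). Saa2 went from 78.5 ± 45.6 to 46023 ± 10189 TPM, Saa1 from 364 ± 214 to 41747 ± 9674 TPM, and the iron-binding protein gene Lcn2 from 186 ± 72.4 to 10214 ± 1836 TPM. In the other direction Cyp2c29, a cytochrome P450 of xenobiotic metabolism, fell from 3487 ± 609 to 37.5 ± 15.1 TPM, a log2 change of -6.59 ± 0.25 (SE; limma adjusted p = 1.04e-09). All 6 SAP values lay outside the range of the 6 control values for each of these genes, as the rule for naming them required.

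Of 11344 genes tested, 2211 were higher and 2832 lower in SAP (limma, Benjamini-Hochberg adjusted p under 0.05), and 6301 were not past the threshold. At a log2 change of at least 1 there were 289 higher and 616 lower genes. Separate groups, with no overlap between SAP and control values, were found for 2903 tested genes (25.6%), against 0.216% by chance. The lead of lower over higher genes at any size depended on scaling: there were 2785 higher and 2735 lower genes with TMM-like scaling, and 2950 higher and 2590 lower with quantile normalization. At a log2 change of at least 1, lower genes outnumbered higher ones under both, 555 against 321 and 509 against 365. With a pseudocount of 0.1 there were 434 higher and 752 lower genes at that size.

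**Figure D1:**
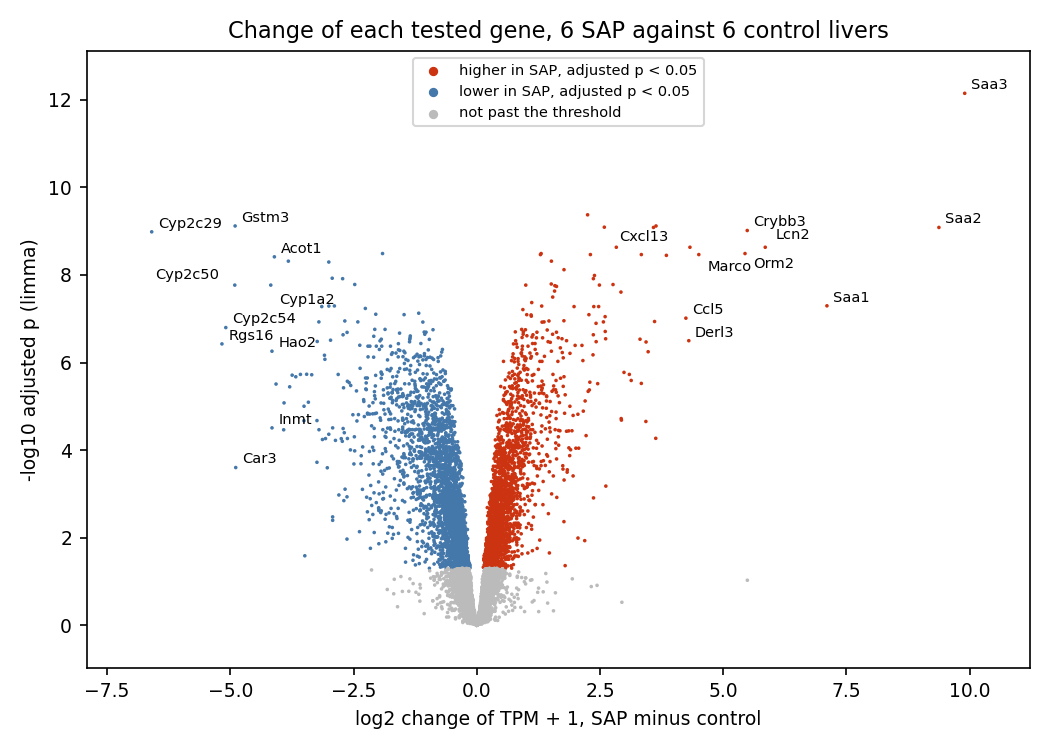
Log2 change of TPM + 1 (x axis, SAP minus control) against -log10 of the limma adjusted p (y axis) for the 11344 tested genes, one point per gene, red for 2211 higher and blue for 2832 lower genes. Saa3 has the largest increase (9.90) and Cyp2c29 the largest decrease (-6.59) among the labelled genes.

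The other genes with the largest increases were Crybb3 (a crystallin, log2 change 5.49), Orm2 (an orosomucoid, 5.44), Marco (a macrophage scavenger receptor, 4.50), the chemokine genes Cxcl13 (4.33) and Ccl5 (4.24), and Derl3 (a component of endoplasmic reticulum protein degradation, 4.30). Decreases after Cyp2c29 were led by Rgs16 (-5.17), Cyp2c54 (-5.09), Cyp2c50 (-4.91), the glutathione transferase gene Gstm3 (-4.90) and the carbonic anhydrase gene Car3 (-4.89). They were followed by Cyp1a2 (-4.18), Hao2 (-4.15), Inmt (-4.15) and Acot1 (-4.11). The size of the Car3 change (SE 0.80) leans on SAP 14, at 5.22 TPM against 40.2 to 420 TPM in the other SAP libraries. In GENCODE M21 on GRCm38, protein-coding Saa3 (46711998 to 46715700), Saa1 (46740497 to 46742980) and Saa2 (46751790 to 46754313) lie near one another on chromosome 7. Cyp2c29 (39269405 to 39330713), Cyp2c54 (40037940 to 40073827) and Cyp2c50 (40089688 to 40113950) lie on chromosome 19. Levels of single members of such families are uncertain, since how reads shared between near-identical copies were assigned is not given in the sources used here.

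The first principal component, with 60.5% of the variance, separated all 6 SAP from all 6 control libraries. Another split ran across the groups. Xist, a nuclear RNA of the inactive X chromosome, was between 4.59 and 17.1 TPM in 5 libraries (control 5, SAP 11, SAP 13, SAP 14 and SAP 15) and between 49.1 and 60.7 TPM in the other 7. Malat1 (2.76 to 8.19 against 26.2 to 40.1 TPM), Neat1 (2.41 to 9.98 against 12.0 to 28.0 TPM) and Firre (1.18 to 3.79 against 8.12 to 11.8 TPM) followed the same split. With both in 1 fit, 309 genes were lower and 10 higher in the low Xist libraries, among the lower ones Ccnl2 (-1.58) and Leng8 (-1.39). With the split as a term, 2324 genes were higher and 2198 lower in SAP. Within the high Xist libraries (5 control, 2 SAP) 2041 were higher and 1830 lower. Of the 2211 higher and 2832 lower genes over all libraries, 1610 and 1785 were past the threshold there in the same direction. Of the 93 named genes past the threshold, 86 were past it there. Those genes were chosen by their change or p-value over all libraries, these included, so their number overstates how well calls hold. The low Xist libraries hold 4 SAP libraries and control 5 alone, so values within them compare with a single library that is assumed to vary like the others, and medians there are given with no p. All 93 named genes had the same direction in both subsets. Where SAP and control values do not overlap, as for all of the largest increases and decreases and most other named genes, that was fixed in advance. It is therefore no test of the split for those genes. The mitochondrially encoded share of TPM was 7.15 ± 0.572% in controls and 5.99 ± 0.752% in SAP (SD, n = 6 each; exact permutation test, adjusted p = 0.0108), with 6.80 to 7.90% against 6.20 to 6.70% in the high Xist libraries and 6.52% against 4.56 to 6.44% in the low Xist libraries. Of the TPM outside the acute-phase list it was 7.32 ± 0.585% in controls and 7.81 ± 0.632% in SAP (SD, n = 6 each; exact permutation test, two-sided, p = 0.193), a measure added after the shares were seen. Without SAP 14 and control 5, which lay lowest on the second component, 2289 genes were higher and 2586 lower.

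**Figure D2:**
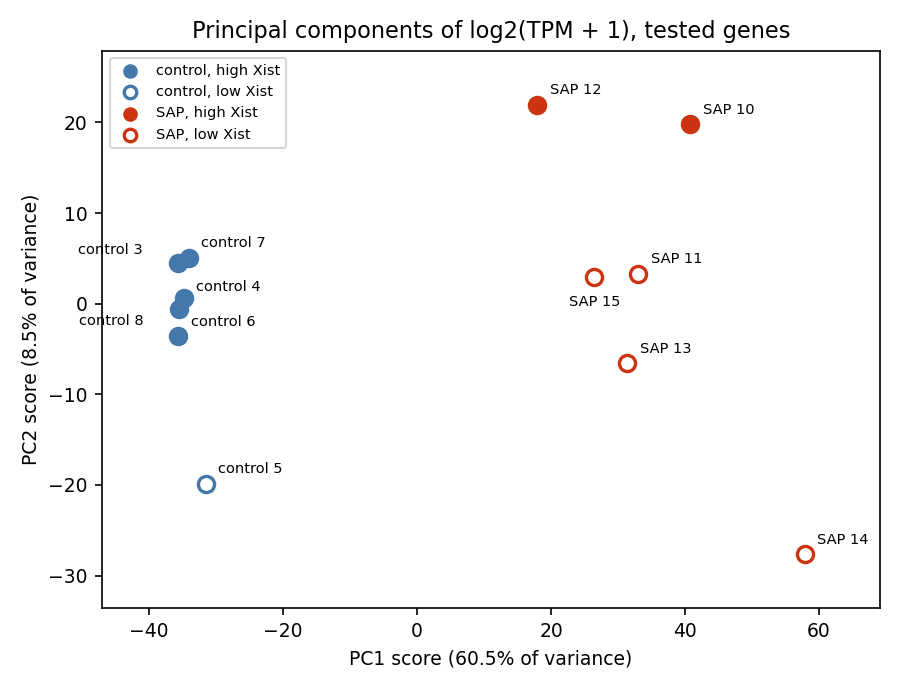
Scores of the 12 libraries on the first (x axis, 60.5% of variance) and second (y axis, 8.5%) principal components of log2(TPM + 1), blue for control and red for SAP, filled for high and open for low Xist libraries. SAP and control separate on the x axis, and control 5 (-19.9) and SAP 14 (-27.6) lie lowest on the y axis.

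Acute-phase genes rose almost as a whole. Of the 24 tested members, 22 rose, 0 fell and 2 were not past the threshold; 23 rose when adjusted over the list alone (camera adjusted p = 2.48e-21; adjusted p = 0.139 with an estimated correlation). Besides the Saa genes, Orm1 reached 16834 ± 3127 TPM from 1344 ± 175 (log2 change 3.64), and Itih4 rose by 2.25 and the fibrinogen gene Fga by 2.57. Crp (0.14) and the hepcidin gene Hamp (1.94, from 819 ± 861 to 2102 ± 1455 TPM) were not past the threshold. The list took up 2.29 ± 0.109% of all TPM (SD, n = 6) in controls and 23.6 ± 4.76% (SD, n = 6) in SAP (exact permutation test, two-sided, p = 0.00216, the smallest it can give; adjusted p = 0.0108). It took 18.7 to 25.2% in the high Xist and 19.7 to 32.0% in the low Xist SAP libraries.

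Of the tested inflammatory signalling and chemokine transcripts, more rose than fell in SAP. In the cytokine and NF-kB list, 10 of 18 tested members rose, 1 fell and 7 were not past the threshold, with the same counts adjusted over the list alone (camera adjusted p = 7.03e-04; adjusted p = 0.244 with an estimated correlation). Socs3, a feedback inhibitor of cytokine signalling, rose by 3.43, the adhesion molecule gene Icam1 by 1.89 and Junb by 1.39. Cebpb fell by 0.69. Among the 7 not past the threshold were Nfkb1 (-0.14), Nfkbia (-0.18) and Nfkb2 (0.27). The list has 23 members, and those not tested reached at most 2.16 TPM in any library. Tnf (at most 0.25 TPM) and Il6 (0 TPM) were among them. Of 17 chemokines 9 were tested, and the others reached at most 5.45 TPM in any library. Among the 9 tested, 5 rose, 1 fell and 3 were not past the threshold, also adjusted over the list alone (camera adjusted p = 0.00426, and adjusted p = 0.174 with an estimated correlation). Cxcl9 rose by 2.61 and Cxcl1 by 2.37, and Ccl9 fell by 0.77. Of 16 interferon-stimulated genes tested, 10 rose, 0 fell and 6 were not past the threshold, with 10 rising adjusted over the list alone (camera adjusted p = 1.32e-04; adjusted p = 0.312 with an estimated correlation). Zbp1 rose by 1.78, Irf7 by 1.70 and Oasl2 by 1.27. The medians of the 3 lists were 0.84, 0.73 and 0.74 within the high Xist and 0.80, 0.90 and 0.58 within the low Xist libraries.

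Most genes of the endoplasmic reticulum stress list were higher in SAP. Of its 16 tested members, 14 rose, 1 fell and 1 was not past the threshold; adjusted over the list alone, 14 rose and 2 fell (camera adjusted p = 4.04e-08; adjusted p = 0.244 with an estimated correlation). Sdf2l1 rose from 57.0 ± 4.34 to 320.1 ± 99.8 TPM (log2 change 2.42), Dnajc3 from 46.1 ± 2.82 to 134 ± 15.4 TPM (1.51) and Hsp90b1 from 301 ± 21.5 to 875 ± 198 TPM (1.51). Trib3 fell by 0.85. The list's median was 1.41 within the high Xist and 1.46 within the low Xist libraries.

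Most of the tested neutrophil and monocyte markers were higher in SAP, from low levels. Of 15 neutrophil markers only 4 were tested, and the others reached at most 1.65 TPM in any library. Among the 4 tested, 3 rose, 0 fell and 1 was not past the threshold, and 4 rose adjusted over the list alone (camera adjusted p = 0.00371, and adjusted p = 0.244 with an estimated correlation). S100a9 went from 4.40 ± 1.97 to 46.8 ± 17.8 TPM, S100a8 rose by 2.93 and Retnlg by 1.39. Of 9 monocyte markers 6 were tested, and the others reached at most 10.5 TPM in any library. Among the 6 tested, 4 rose, 1 fell and 1 was not past the threshold, with the same counts adjusted over the list alone (camera adjusted p = 0.00553, and adjusted p = 0.312 with an estimated correlation). Itgam rose from 0.228 ± 0.149 to 3.98 ± 1.13 TPM, Plac8 by 1.77 and Fcgr1 by 1.01, and Lyz2 fell by 0.45. In the stellate cell and matrix list 6 of 11 tested members rose, 1 fell and 4 were not past the threshold, also adjusted over the list alone (camera adjusted p = 0.0250; adjusted p = 0.380 with an estimated correlation). Timp1, an inhibitor of matrix metalloproteinases, rose from 0.293 ± 0.228 to 12.1 ± 2.64 TPM, Col1a1 rose by 0.60 and Reln fell by 1.22. That list had a median of 0.61 within the high Xist (adjusted p = 0.0158) and 0.08 within the low Xist libraries. With a mean of at least 5 TPM neither the monocyte nor the stellate list was past the threshold (adjusted p = 0.167 and 0.159). Monocyte medians were 1.21 and 0.53, and neutrophil medians 1.85 and 2.08.

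Kupffer cell markers went apart. Marco rose from 0.975 ± 0.421 to 44.9 ± 16.5 TPM, while Clec4f fell by 0.69 and Timd4 by 0.59. Of 11 tested markers 1 rose, 3 fell and 7 were not past the threshold, also adjusted over the list alone. The list was not past the threshold (camera adjusted p = 0.995), and its mean (0.22) differed in sign from its median (-0.07) and from the test. Clec4f and Timd4 were not past the threshold with the Xist split as a term (adjusted p = 0.0548 and 0.0902) or within the high Xist libraries (0.537 and 0.590). Of 12 sinusoidal endothelium markers 4 rose, 1 fell and 7 were not past the threshold, also adjusted over the list alone, and the list was not past the threshold (camera adjusted p = 0.229; adjusted p = 0.0178 within the high Xist libraries). Lyve1 rose by 1.25 and Stab1 by 0.71, and Bmp2 fell by 0.66 (-0.38 and not past the threshold within the high Xist libraries, adjusted p = 0.0618). Of 9 cholangiocyte markers 3 were tested, and the others reached at most 1.68 TPM in any library. None of the 3 was past the threshold, with 0 rising and 0 falling adjusted over the list alone (camera adjusted p = 0.943). The log2 differences were -0.30 ± 0.12 (SE) for Krt19 and 0.14 ± 0.22 for Spp1. Krt19 was past the threshold with quantile normalization (adjusted p = 0.0408) and without control 6 (0.0299), SAP 10 (0.0495) or SAP 11 (0.0488). Another 3 lists had 1 tested member each and no list test, so adjustment over the list alone adds nothing there. The lymphocyte gene Gzma (1 of 13 members tested) rose by 0.87 and the adipocyte gene Fabp4 (1 of 6) by 1.09. Cela1 of the pancreatic acinar list (1 of 16) fell by 1.73. It averaged 52.9 ± 9.62 TPM in controls, where the other acinar transcripts summed to 0.89 to 19.16 TPM, so it does not stand for that list.

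**Figure D3:**
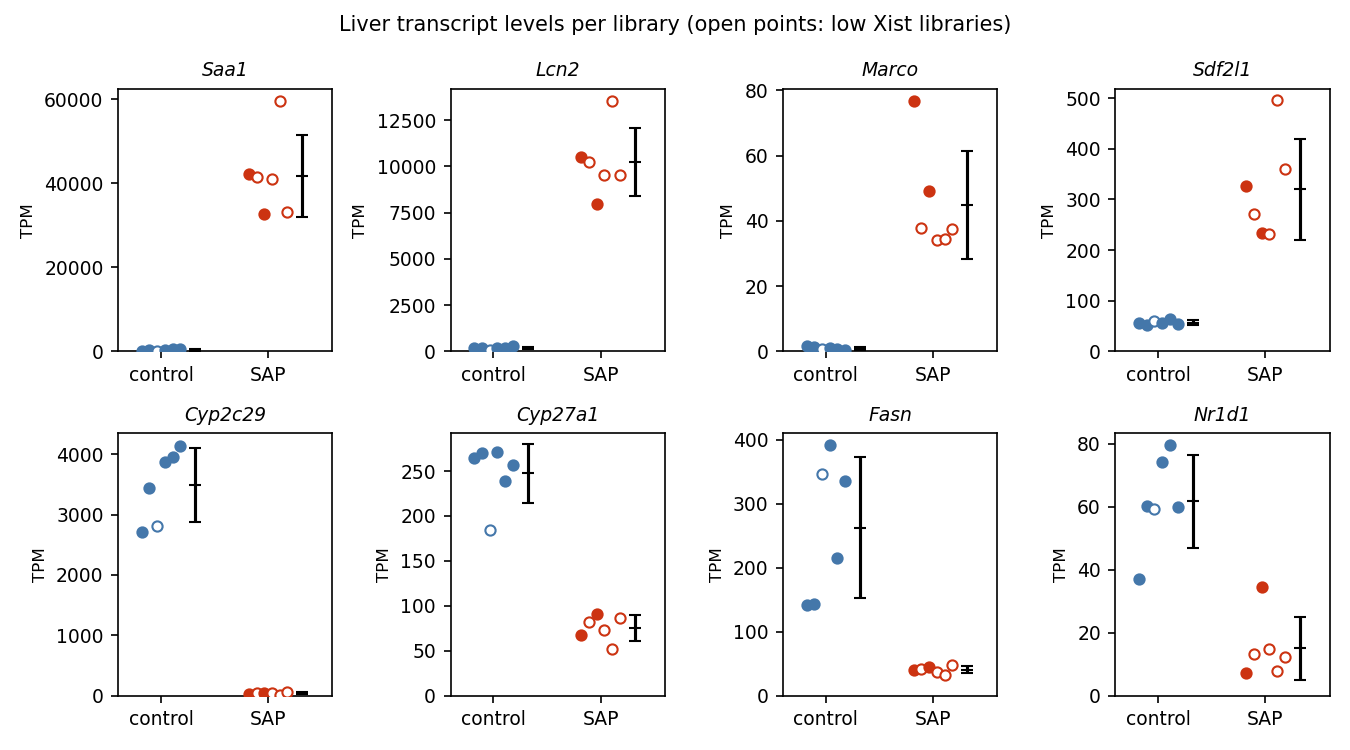
TPM (y axes, linear from 0) of 8 named genes in each of the 6 control and 6 SAP libraries, one point per library, open for low Xist libraries, with the mean and SD as black bars. Saa1, Lcn2, Marco and Sdf2l1 are higher, and Cyp2c29, Cyp27a1, Fasn and Nr1d1 lower, in every SAP library than in every control library.

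Drug-metabolising enzymes fell most among the metabolic lists. Of 21 tested members 20 fell, 1 rose and 0 were not past the threshold, also adjusted over the list alone (camera adjusted p = 4.16e-10; adjusted p = 0.244 with an estimated correlation). The median log2 change was -2.28, with -2.12 within the high Xist and -2.48 within the low Xist libraries. Cyp1a2 fell from 692 ± 53.2 to 39.7 ± 14.4 TPM and Cyp2c50 from 530.4 ± 36.6 to 18.4 ± 8.73 TPM, and Cyp3a13 rose by 0.49.

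Transcripts for bile acid handling fell as well. In that list 15 of 20 tested members fell, 0 rose and 5 were not past the threshold, also adjusted over the list alone (camera adjusted p = 2.43e-05; adjusted p = 0.312 with an estimated correlation). Cyp27a1, which starts the acidic pathway of bile acid synthesis, fell from 247 ± 33.2 to 75.4 ± 14.4 TPM (-1.71), the bile acid ligase gene Slc27a5 fell by 1.16 and the conjugating enzyme gene Baat by 0.62. Cyp7a1, the rate-limiting enzyme of the classic pathway, fell from 28.3 ± 32.9 to 4.75 ± 8.95 TPM (-2.63). The list was also past the threshold within the high Xist libraries (adjusted p = 6.49e-07).

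Most tested genes of fatty acid synthesis, fatty acid oxidation, glucose metabolism and the urea cycle list fell. All 13 tested genes of fatty acid synthesis fell, with 0 rising and 0 not past the threshold, also adjusted over the list alone (camera adjusted p = 4.77e-08; adjusted p = 0.244 with an estimated correlation). Fasn, the fatty acid synthase, fell from 263 ± 109.8 to 40.7 ± 5.74 TPM (-2.56), Acly by 1.81 and Gpam by 1.63. Of 23 genes of fatty acid oxidation and PPAR-alpha targets 15 fell, 3 rose and 5 were not past the threshold, also adjusted over the list alone (camera adjusted p = 1.93e-04; adjusted p = 0.340 with an estimated correlation). Ehhadh fell by 2.26 and Cyp4a10 by 2.07, and Vnn1 rose by 1.69. Glucose and glycogen metabolism had 12 of 14 tested members lower, 0 higher and 2 not past the threshold, also adjusted over the list alone (camera adjusted p = 1.89e-05; adjusted p = 0.244 with an estimated correlation). Glycogen phosphorylase Pygl fell by 1.89, pyruvate kinase Pklr by 1.76 and the gluconeogenic enzyme Pck1 by 1.62. In the urea cycle and amino acid list 16 of 17 tested members fell, 0 rose and 1 was not past the threshold, also adjusted over the list alone (camera adjusted p = 4.77e-08; adjusted p = 0.244 with an estimated correlation). Cps1, the entry enzyme of the urea cycle, fell from 1273 ± 175 to 282 ± 76.3 TPM, Gls2 by 1.98 and Asl by 1.59. Medians of the 4 lists were -1.55, -0.39, -1.10 and -1.66 within the high Xist and -2.28, -0.48, -0.96 and -1.26 within the low Xist libraries.

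Some genes of the hepatocyte identity and cell division lists were lower in SAP. Of 15 tested genes of hepatocyte identity and secreted proteins 7 fell, 2 rose and 6 were not past the threshold, also adjusted over the list alone (camera adjusted p = 0.0361; adjusted p = 0.482 with an estimated correlation). Alb, the albumin gene, fell from 65029 ± 4415 to 27673 ± 4277 TPM (-1.24), Serpina1a by 1.48 and Apoa2 by 1.13, while Foxa2 rose by 0.85. Hnf4a, with a log2 difference of 0.18 ± 0.10 (SE), was not past the threshold. The list was not past the threshold without SAP 14 (adjusted p = 0.0575) or with a mean of at least 5 TPM (0.0858). Of 16 cell division genes 7 were tested, and the others reached at most 2.41 TPM in any library. Among the 7 tested, 4 fell, 0 rose and 3 were not past the threshold, also adjusted over the list alone (camera adjusted p = 0.0437, and adjusted p = 0.327 with an estimated correlation). Those that fell, Mcm6 by 1.27, Mcm5 by 0.83, Mcm2 by 0.65 and Pcna by 0.29, encode DNA replication factors. That call ended on leaving out any one of control 5 (adjusted p = 0.0683), SAP 10 (0.0513), SAP 11 (0.0536), SAP 12 (0.0591) or SAP 14 (0.0557), with no filter (0.129), and within the high Xist libraries (0.0778), where Mcm5 was not past the threshold either (-0.61, adjusted p = 0.113).

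Haemoglobin transcripts were lower in SAP, with controls far apart. All 5 tested erythroid members fell, with 0 rising and 0 not past the threshold, also adjusted over the list alone (camera adjusted p = 0.0190; adjusted p = 0.380 with an estimated correlation). Hbb-bs averaged 1231 ± 747 TPM (SD, n = 6) in controls and 228 ± 60.5 TPM (SD, n = 6) in SAP, Hba-a2 fell by 2.22 and Hbb-bt by 2.70. Among controls Hbb-bs was 247 TPM in control 5 and 385 TPM in control 4, against 1417 to 2079 TPM in the other 4. The list was past the threshold within the high Xist libraries (median -2.75, camera adjusted p = 0.00231). In the low Xist libraries its median was -0.10, but the only control there is control 5, whose Hbb-bs was the lowest among controls.

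Clock genes changed in both directions. Of 16 tested members 4 rose, 9 fell and 3 were not past the threshold; adjusted over the list alone, 5 rose and 9 fell (camera adjusted p = 0.405). Nr1d1, a repressor of the clock loop, fell from 61.8 ± 14.8 to 15.0 ± 10.1 TPM (-2.11), Dbp by 1.84 and Nr1d2 by 0.77, while Cry1 rose by 1.22 and Arntl by 0.93. Within the high Xist libraries Nr1d2 was not past the threshold (-0.56, adjusted p = 0.0931).

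The remaining lists were mixed and were not past the threshold as lists. Complement and coagulation had 7 risen, 9 fallen and 8 of 24 not past the threshold, and 7 risen and 10 fallen adjusted over the list alone (camera adjusted p = 0.738); its mean (0.02) and its median (-0.17) differed in sign. Fgl1 rose by 2.37, and the mannose-binding lectin gene Mbl2 fell by 1.75. Oxidative stress genes and metallothioneins had 5 risen, 6 fallen and 2 of 13 not past the threshold, and 6 risen and 6 fallen adjusted over the list alone (camera adjusted p = 0.995). Mt1, a metallothionein, rose from 560.4 ± 229 to 4704 ± 1473 TPM, while the glutathione transferase genes Gsta2 and Gsta1 fell by 3.09 and 2.81. Cholesterol synthesis had 2 risen, 7 fallen and 13 of 22 not past the threshold, and 1 risen and 7 fallen adjusted over the list alone (camera adjusted p = 0.0711). It was past the threshold with no filter (adjusted p = 0.0144) and without control 3 (adjusted p = 0.0282) or control 7 (0.0111). Sc5d fell from 201 ± 41.9 to 80.3 ± 12.6 TPM, Insig1 by 1.18 and Stard4 by 0.64 (-0.38 and not past the threshold within the high Xist libraries, adjusted p = 0.0551).

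Of 12 tested p53 targets and cell death genes 6 rose, 2 fell and 4 were not past the threshold, also adjusted over the list alone (camera adjusted p = 0.0639; 0.0489 without SAP 12 and 0.00334 with no filter). Gadd45g rose by 3.48 and the death receptor gene Fas by 0.90, and Bbc3 fell from 9.75 ± 1.02 to 4.58 ± 1.71 TPM. Among immediate early and heat shock genes 5 of 10 rose, 1 fell and 4 were not past the threshold, also adjusted over the list alone (camera adjusted p = 0.0531). The list was past the threshold without control 5 (adjusted p = 0.0314), control 6 (0.0455), control 7 (0.0424), SAP 11 (0.0384) or SAP 15 (0.0494). Ier3 rose by 1.21, Hsph1 by 0.72 and Myc by 0.40 (0.33 and not past the threshold within the high Xist libraries, adjusted p = 0.111). The list of growth hormone axis and male-biased liver genes had 1 of 11 tested members risen, 6 fallen and 4 not past the threshold. Counts were the same adjusted over the list alone. The camera adjusted p was 0.173, or 0.0167 with no filter and 0.0206 with a mean of at least 5 TPM. Ghr, the growth hormone receptor gene, fell by 1.04 and Igf1 by 0.70, and Cish rose by 1.89.

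Of the 27 lists tested, 17 were past the threshold with the preset correlation of camera, and 0 with an estimated correlation. The fry test of direction, which sets a list against no change and not against other genes, gave 20. Of 100 splits of the 12 libraries into 6 and 6, the real one included, 5 gave at least 17 lists with the preset correlation, while the 44 splits that share 3 of 6 libraries per group with the real one gave at most 9. The other 4 with at least 17 share 4 or 5 libraries per group with it, and gave 0 genes past the threshold in either direction.

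**Figure D4:**
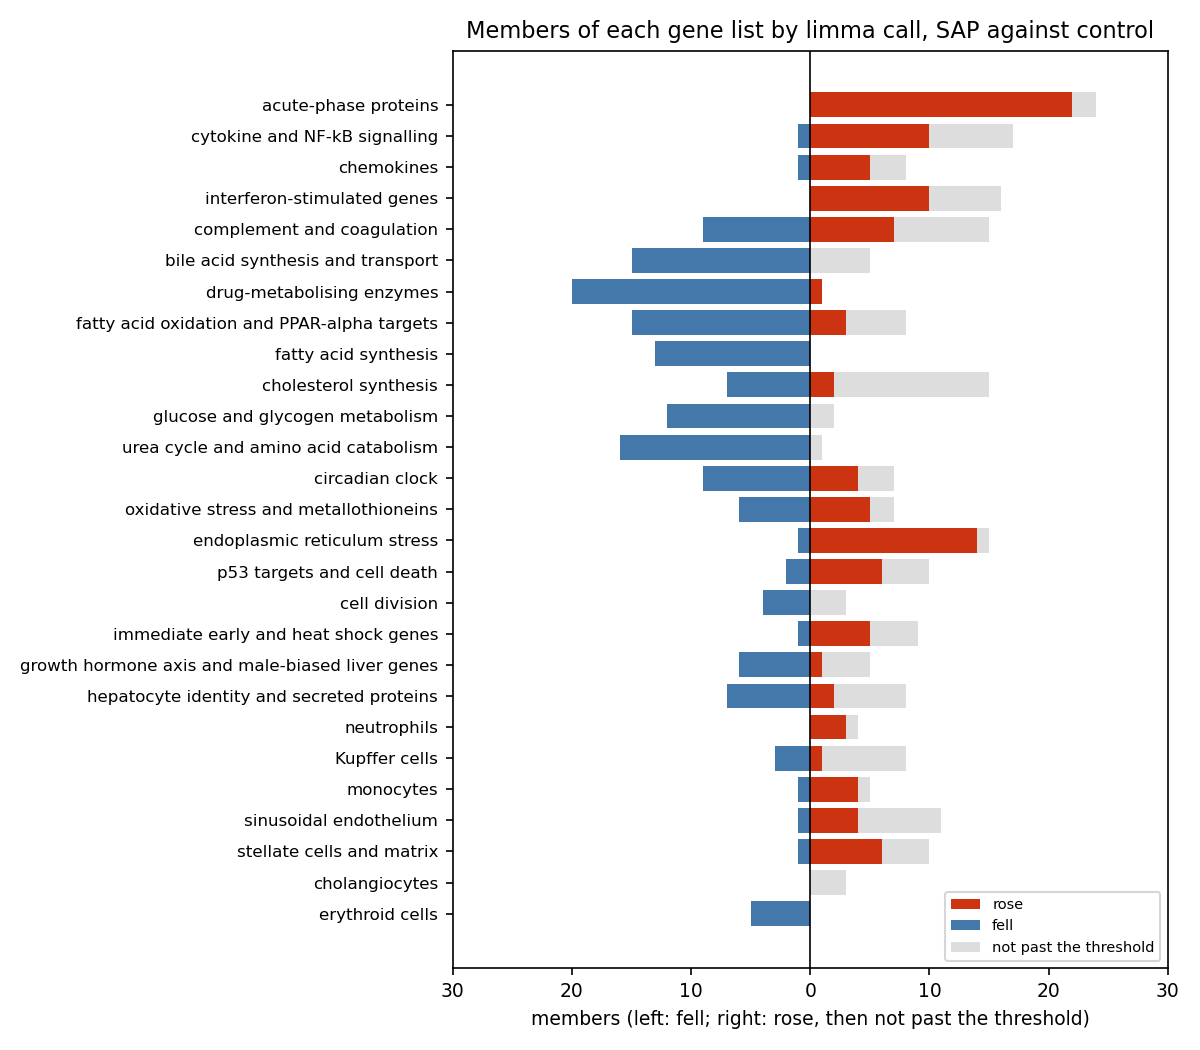
Number of members (x axis) that fell (blue, left), rose (red, right) or were not past the threshold (grey) in each of the 27 tested lists (y axis). The acute-phase list has 22 of 24 members risen, and the drug-metabolising list has 20 of 21 fallen.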

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

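The tests of the low Xist libraries against treatment and sex were chosen only after the result was seen; the test of other long non-coding genes was written before its result. Of 210 groups of 6 values examined, 9 (4.29%) held a library far from the other 5, where chance gives about 5%.

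Control 5 stood apart from the other controls in Xist (10.15 TPM, others 49.1 to 59.9), Malat1 (7.24 TPM, others 26.2 to 39.9), the second principal component (-19.9, others -3.59 to 5.07) and Cyp27a1 (183.9 TPM, others 239 to 271.0). SAP 14 stood apart from the other SAP libraries in Derl3 (226.9 TPM, others 158 to 179) and in the share of TPM held by its 10 highest genes (31.1%, others 24.5 to 26.2%). SAP 10 was high in Gzma (3.52 TPM, others 1.04 to 1.74). Control 8 was high in Itgam (0.52 TPM, others 0.12 to 0.22) and in the sum of pancreatic acinar transcripts other than Cela1 (19.16 TPM, others 0.89 to 2.40), with Ctrb1 at 4.54, Prss2 at 2.23 and Pnlip at 1.51 TPM.

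Low Xist, Malat1, Neat1 and Firre marked 5 libraries, control 5 and SAP 11, 13, 14 and 15. Treatment alone would place all SAP libraries and no control among them, and 3 libraries were out of place (Fisher's exact test, p = 0.242). Male animals are argued against by Y-linked genes, which reached at most 0.10 TPM in these libraries and in the others. A smaller share of nuclear RNA may account for the split and stays open: the 403 other long non-coding genes tested had a median difference of -0.13 against -0.10 for the remaining genes, a difference that was not past the threshold with camera. No biological explanation other than treatment and sex was tested.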

How the results depend on the processing

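The Xist settings, the setting without SAP 14 and control 5, and the highest-mean rule were chosen only after the data were seen; the others were planned. Values are adjusted p of lists unless called genes. Of named gene results across alternatives, 2232 kept direction and side of the threshold, 48 lost the threshold (39 in the low Xist libraries alone, 7 in the high Xist libraries and 2 with the Xist term), 4 (all Krt19) passed it and 2 (both Spp1) reversed. Limma without trend and TMM-like scaling moved no list call or direction. The robust step does not enter the list test, so it could not move a list. The highest-mean rule moved no list call either, but it changed the row of only 1 tested gene, Ddit3. No paired analysis was possible because the groups share no replicate numbers. Alternatives for counts were not run because the values are TPM, and how depth limits low genes is unknown. Except where fewer genes or libraries were tested, the cause was not tested.

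With an estimated correlation all 17 called lists lost the threshold: acute-phase 0.139, chemokines 0.174, cytokine, drug-metabolising, fatty acid synthesis, glucose, urea cycle, endoplasmic reticulum stress and neutrophils 0.244, interferon, bile acid and monocytes 0.312, cell division 0.327, fatty acid oxidation 0.340, stellate and erythroid 0.380, and hepatocyte identity 0.482. With fry for direction, complement (0.837), Kupffer (0.451) and cholangiocytes (0.975) reversed, and p53 (7.78e-06), immediate early (0.00109) and growth hormone (0.00805) passed. With fry for any change, complement and p53 (1.79e-09), cholesterol (1.94e-05), clock (9.57e-06), oxidative stress (8.27e-09), immediate early (2.87e-07), growth hormone (1.94e-07), Kupffer (2.00e-12) and endothelium (1.62e-06) passed, and erythroid did not (0.0675).

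Quantile normalization reversed complement (0.494), oxidative stress (0.920) and Kupffer (0.957), none past the threshold. With no filter cholesterol (0.0144), p53 (0.00334) and growth hormone (0.0167) passed and cell division did not (0.129). With a mean of at least 5 TPM, growth hormone passed (0.0206), hepatocyte identity (0.0858), monocytes (0.167) and stellate (0.159) did not, and oxidative stress and Kupffer reversed (0.672 each). A pseudocount of 0.1 gave 434 genes higher and 752 lower at least 2-fold and reversed oxidative stress (0.968).

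The Xist term reversed Kupffer (0.602). The high Xist libraries gave 1830 lower genes, lost cell division (0.0778), passed endothelium (0.0178) and reversed Kupffer (0.110). The low Xist libraries have control 5 as their only control, assumed to vary like the others, so their gains and losses show neither presence nor absence of a change. They gave 159 higher and 204 lower genes, 147 and 193 at least 2-fold; cholesterol (0.0200) and p53 (0.0207) passed, stellate (0.511) and erythroid (0.856) did not, and oxidative stress (0.764), cholangiocytes (0.683) and Spp1 (log2 -0.47) reversed. Without SAP 14 and control 5, cell division (0.0789) and hepatocyte identity (0.0729) were lost, immediate early passed (0.0487), and oxidative stress (0.982) and Kupffer (0.788) reversed.

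Leaving out each library gave 1955 to 2453 higher and 2536 to 3063 lower genes. List ranges were 0.432 to 0.972 for Kupffer, 0.891 to 0.991 for oxidative stress, 0.778 to 0.991 for cholangiocytes, 0.0282 to 0.0683 for cell division, 0.0111 to 0.212 for cholesterol, 0.0277 to 0.0575 for hepatocyte identity, 0.0314 to 0.0836 for immediate early and 0.0489 to 0.0996 for p53. Spp1 (log2) ranged from -0.014 to 0.27.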

Other observations

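The gene families and the tests of the clock genes and of the excess of lower genes were chosen only after the results were seen; the counts over other splits were planned. Subunits of mitochondrial oxidative phosphorylation were lower in SAP: of 79 tested, 73 fell and 1 rose, with a median log2 change of -0.50 (camera adjusted p = 4.46e-23; adjusted p = 0.0797 with an estimated correlation), -0.44 with TMM-like scaling and -0.19 with quantile normalization. Sdhb fell by 1.18, Cyc1 by 1.09 and Cox5a by 0.89. A larger acute-phase share (2.29% of TPM in controls, 23.6% in SAP) by itself lowers the TPM of other genes. How much of the -0.50 it makes up was not tested. Of 84 cytosolic ribosomal proteins 65 rose and 1 fell (median 0.30; camera adjusted p = 3.70e-15; adjusted p = 0.287 with an estimated correlation), and the median was 0.36 with TMM-like scaling and 0.58 with quantile normalization, with Rplp0 up by 0.77. The machinery for secreted proteins was higher: 21 of 25 genes of protein translocation and signal peptidase rose and 0 fell (median 0.72), among them Ssr3 (1.18) and Ssr4 (1.11), as did 14 of 23 genes of N-glycosylation, with 0 falling (median 0.64; Stt3b 0.91), and 26 of 37 genes of vesicle coats, with 4 falling (median 0.44; Tmed4 0.94). The 3 had camera adjusted p = 2.32e-13, 1.31e-08 and 1.26e-08, and adjusted p = 0.0797 each with an estimated correlation.

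Families of detoxification, which share members with the fixed lists, were lower: 17 of 20 glutathione S-transferases fell and 1 rose, 34 of 38 cytochrome P450 genes of families 2 and 3 fell and 1 rose, and 10 of 10 UDP-glucuronosyltransferases fell (camera adjusted p = 2.58e-10, 1.50e-13 and 1.79e-05; adjusted p = 0.0797, 0.147 and 0.218 with an estimated correlation). Without the 3, 13 and 3 members that a fixed list holds, 14 of 17, 23 of 25 and 7 of 7 fell (camera adjusted p = 2.32e-08, 1.28e-09 and 7.64e-04; adjusted p = 0.0918, 0.133 and 0.226 with an estimated correlation). Of 18 major urinary protein genes, which are near-identical copies, 17 fell (3.60e-05; adjusted p = 0.385 with an estimated correlation). MHC class I genes went both ways, with 6 of 19 risen and 2 fallen (0.0146; adjusted p = 0.466 with an estimated correlation): H2-D1 rose by 0.67, and B2m fell by 0.72 and H2-Q10 from 876 ± 69.0 to 442 ± 66.4 TPM. Of 5 MHC class II genes 4 fell (0.0841), with a median of -1.11, and -0.47 within the high Xist libraries. Not past the threshold were proteasome subunits (2 of 37 risen, 9 fallen, 0.340; median -0.07, and 0.20 with quantile normalization), tRNA synthetases (3 of 33 risen, 12 fallen, 0.0675) and peroxisome biogenesis (2 of 16 risen, 8 fallen, 0.0503). Reg3g was listed at 0 in all controls and at 0.29 to 1.67 TPM in SAP.

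For 100 splits of the 12 libraries into 6 and 6, drawn from 462 and including the real one, genes were counted in the larger direction of each split. Only 1 split, the real one, reached its 2211 higher genes, and only 1 its 2832 lower genes (highest other 1044). At least 2-fold, 2 splits reached the 289 of the higher genes and 1 the 616 of the lower genes (highest other 296). Counts of 1 or 2 in 100 make chance an unlikely source, but 100 splits cannot exclude it. The split with 296 genes shared 5 of 6 libraries per group with the real one. For lists, 5 splits gave as many (17, highest other 19), so chance cannot be excluded for that number by this count. The 4 others share 4 or 5 of 6 libraries per group with the real split and so hold part of its difference, while the 44 splits that share 3 gave at most 9 lists.

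More genes fell than rose at least 2-fold, by 327. Under TMM-like scaling an excess of 234 remained (207 to 261 with each library left out). That scaling centres each library on its typical gene and does not remove the TPM that acute-phase transcripts took up. Genes were not counted over the TPM outside the acute-phase list, so whether that share accounts for the excess stays open. The difference between low and high Xist libraries does not account for all of the excess, but may account for part. With the split as a term 202 remained (99 to 281 with each library left out). In the high Xist libraries 102 remained (71 to 109 with each control left out). At any size the excess was 621, and it was -50 under TMM-like scaling (-54 to 46) and -126 with the Xist split as a term (-389 to 155; -211 in the high Xist libraries). Both explanations stay open there.

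Clock genes were set apart by phase of peak, after their directions had been seen. The 10 tested genes that peak in the light phase had a median of -0.73, with 9 lower. The 6 that peak in the dark phase or at dawn had a median of 0.52 (0.44 to 0.62 with each library left out), with 4 higher. Those 4 show that not every tested clock transcript fell. The medians cannot test a general fall, since the sets were formed with the directions known. The medians differed by -1.25, or by -1.72 over the 11 clearest members. Within the high Xist libraries, where the split is absent, a difference of -1.23 remained. Those libraries are part of the data in which the directions were seen, so this is no independent test of the split. Livers collected at another time of day may give such a pattern, but sets chosen in this way cannot decide it, and an effect of treatment on the clock was not tested.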
